A study of Homo sapiens with 16 samples.

How the data were processed

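RNA from SW480 cells was measured on 16 Affymetrix U133 Plus 2.0 arrays, 4 in each of 4 groups, with replicates lettered A to D. The authors deposited 1 table with a value per probe set and array. Its values are log2 expression levels made by the authors with RMA, which corrects the background, quantile-normalises the arrays and summarises each probe set; the submitters' processing notes name RMA without a version. The log base was read from the values, which ran from 1.8 to 14.56, had no gaps and were rounded to 2 decimals. Quantile normalisation forces the arrays to like distributions, so a change in total RNA per cell could not be seen. A signal on these arrays has no count behind it, and the number of arrays limits the precision. The labels call the samples biological replicates without stating separate cultures, so p-values measure only the spread between these samples, which may be technical. The labels also do not say whether the APC arrays come from 1 stable line or several.

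Of the 54675 probe sets, 42898 were in the probe annotation, 41097 were paired there with 1 gene, 1801 with several and 11777 with none. Gene symbols were looked up through the gene ID for 41043 probe sets and kept as annotated for the other 54, and 0 symbols changed. Each of the 19775 genes was represented by the probe set with the highest mean over all arrays; 10523 genes had several probe sets. No filter on dim probe sets was applied. Genes are given by symbol, and no genome positions are given because no reference genome was used here.

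Groups, comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. All 16 arrays entered 1 linear model in limma 3.58.1 (R 4.3.3), with lmFit, eBayes with its default prior and no block. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, and adjusted p-values for genes are from this limma fit. The 5 comparisons were siTAZ, sibcat and APC cells each against control, and siTAZ and APC cells each against sibcat cells. Levels of single genes and of RNA quality measures were also compared by exact two-sided permutation tests, whose smallest possible p with 4 against 4 arrays is 0.0286. Figures were drawn with matplotlib 3.10.9.

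The 29 gene lists held 687 genes, of which 640 were analysed and 47 had no single-gene probe set. They covered YAP/TAZ target genes, Wnt/beta-catenin target genes, Hippo pathway and TEAD components, Wnt pathway components, intestinal stem cell markers, enterocyte differentiation markers, goblet and Paneth cell markers, enteroendocrine and tuft cell markers, epithelial junction and keratin genes, mesenchymal genes, focal adhesion and actin cytoskeleton genes, extracellular matrix and secreted protease genes, TGF-beta and BMP response genes, DNA replication and G1/S genes, mitosis and G2/M genes, cyclin-dependent kinase inhibitors and p53 targets, ribosome biogenesis genes of the MYC programme, cholesterol biosynthesis genes, glycolysis and hypoxia response genes, oxidative phosphorylation genes, unfolded protein and amino acid stress response genes, interferon response genes, NF-kappaB and inflammatory genes, immediate early and MAPK feedback genes, apoptosis and survival genes, RNA interference machinery genes, and markers of fibroblasts and endothelium, of leukocytes and of nervous system and liver. Lists were written from general knowledge of these pathways. Each was tested with camera, which compares a list with all other genes, at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 87 tests in the comparisons with control. Each test was repeated with the inter-gene correlation estimated from the data, and with fry, which asks whether a list's own genes move one way on balance. Counts of changed members are given after adjustment over all genes and adjusted over the list alone. The lists were also tested in the comparisons with sibcat cells, in 58 tests chosen after the results against control had been seen.

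Named genes were WWTR1, CTNNB1, APC and YAP1; the 8 largest increases and 8 largest decreases per comparison with control among changed genes whose groups did not overlap and whose brighter group reached the median probe set level of 5.10; the 4 most changed members of each target list and up to 3 of every other list past camera; the 5 genes changed most in both of a pair of comparisons, per direction; and the 4 highest and 4 lowest against sibcat. The rule gave 170 genes. Where a gene's mean in either group compared lay below 5.10, the signal there may be largely background; its log2 difference is given as measured, and its size and rank are uncertain. Genes named outside it are described as chosen after their values were seen.

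Genes shared between comparisons with the same controls were set beside the product of the counts divided by 19775, beside 50 simulations of unchanged groups against shared controls, and beside all 6 ordered splits of the controls into 2 and 2. The fit was tested on simulated data for siTAZ versus control, in which 200 of 19775 genes were given a change: 30% of changes of 0.25 on the log2 scale, 88% of those of 0.5 and 100% of those of 1 and of 2 were called, with 10 false calls. The simulated noise was independent between arrays and genes, and far fewer genes changed than the 5951 called in siTAZ cells. The shares therefore check the fit and do not give the recovery in these data.

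Alternatives chosen in advance were a fit to only the groups compared, a replicate block, a variance prior with trend, only genes at or above the median level, the mean of a gene's probe sets, no probe sets with the endings that Affymetrix gives to probes shared between transcripts or genes, cyclic loess, array weights, an adjusted p under 0.01, a minimum change of 1.5-fold, and leaving out each array in turn. Added after seeing the data were a block of replicates A and B against C and D, fits to A and B alone and to C and D alone, other splits of the arrays with that block, and the difference between 3' and 5' probe sets of ACTB as a covariate. The closing section gives their effect. No array was left out.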

Results

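Gene expression was measured in SW480, a human colorectal cancer cell line whose APC gene is truncated and in which beta-catenin is therefore active without a Wnt signal. The 16 arrays fell into 4 groups of 4: control cells, with an empty vector and a control siRNA against GFP; siTAZ cells, in which an siRNA targeted TAZ (gene WWTR1), a transcriptional partner of the TEAD factors; sibcat cells, in which an siRNA targeted beta-catenin (gene CTNNB1), the effector of Wnt signalling; and APC cells, which stably carried wild-type APC and received the control siRNA. The series asks what TAZ contributes to Wnt signalling. Each comparison with control therefore asks which genes change with the siRNA against TAZ, with the siRNA against beta-catenin or in cells carrying APC. The comparisons with sibcat cells ask which responses set siTAZ or APC cells apart from sibcat cells. Each target had 1 siRNA condition, so effects of an siRNA on other genes are not separated from loss of its target. All 16 arrays entered 1 fit, in which 19775 genes were tested.

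The siRNAs lowered their targets. WWTR1 stood at 10.28 ± 0.11 (SD, n = 4) on the log2 scale in control cells and at 6.91 ± 0.15 in siTAZ cells, a fall by 3.37 (SE 0.07), which left 9.66% of the control signal (limma adjusted p = 8.87e-15; exact two-sided permutation p = 0.0286). All 3 of its probe sets fell. CTNNB1 went from 13.12 ± 0.16 to 10.16 ± 0.24 in sibcat cells, leaving 12.9% (log2 change -2.96, SE 0.11, adjusted p = 2.18e-12, exact two-sided permutation p = 0.0286). Another of its probe sets fell by only 0.40 in sibcat cells, leaving 75.7%. The APC gene gave a mixed picture in APC cells: its brightest probe set differed by 0.08 (adjusted p = 0.709), while 2 of its 5 probe sets rose by 0.41 and 1.11, and the mean of its probe sets was higher by 0.35 (adjusted p = 9.99e-04). Which of them lie within the introduced sequence was not known, so the 0.08 does not show whether it was expressed. CTNNB1 mRNA fell by 0.38 in APC cells (adjusted p = 0.0126) and differed by 0.20 in siTAZ cells (adjusted p = 0.196), a difference that passed the test with the replicate block. The CTNNB1 probe set with the small fall in sibcat cells rose by 0.40 in siTAZ cells (limma adjusted p over all probe sets = 0.00126). WWTR1 rose by 0.70 in sibcat cells (adjusted p = 7.45e-07) and by 0.73 in APC cells (adjusted p = 5.05e-07), although another of its probe sets did not change past the threshold in either group (-0.22 and 0.07). YAP1, the paralog of TAZ, fell by 1.32 in sibcat cells (adjusted p = 1.51e-09) and by 0.76 in APC cells (adjusted p = 1.31e-06). It differed by -0.17 in siTAZ cells (adjusted p = 0.157). In siTAZ cells the YAP1 difference passed the test without control replicate B (-0.24) and in replicates C and D alone (-0.32). Another YAP1 probe set passed in siTAZ cells (-0.24, limma adjusted p over all probe sets = 0.0306), while a further one differed by 0.03 and did not pass.

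**Figure D1:**
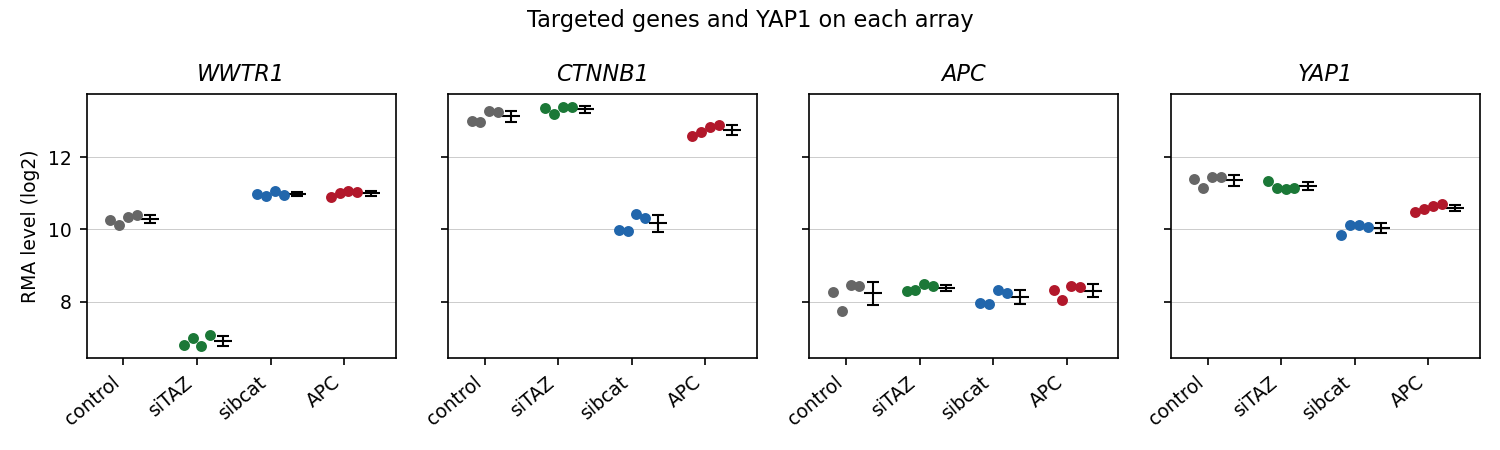
Log2 RMA level of WWTR1, CTNNB1, APC and YAP1 on each of the 16 arrays by group, with 4 points per group and the mean ± SD beside them. WWTR1 is lowest in siTAZ cells (mean 6.91), CTNNB1 in sibcat cells (mean 10.16), and YAP1 is lower in sibcat and APC cells than in control cells (control mean 11.36).

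The siRNA against TAZ lowered the textbook YAP/TAZ target CCN2 (log2 change -2.49, SE 0.13, n = 4 per group, adjusted p = 4.34e-10). CCN2 was among the 12 of 25 analysed YAP/TAZ target genes that fell. CCN2 also fell in sibcat and APC cells against the same control arrays, so its fall was not particular to siTAZ cells. Interferon response genes were higher (median 0.17). This list was also called higher in sibcat (median 0.48) and APC cells (median 0.40), against the same control arrays. Its rise was therefore not particular to siTAZ cells. The CCN2 mean of 4.77 in siTAZ cells lay below the median probe set level of 5.10, so the size of its fall is uncertain. Camera also called the YAP/TAZ target list and 2 cell-cycle lists lower and inflammatory genes higher, but these calls were lost with an estimated correlation. The adjusted p with an estimated correlation was 0.0597 for YAP/TAZ target genes, 0.117 for DNA replication genes, 0.0727 for mitosis genes and 0.0621 for inflammatory genes, against 0.00975 for interferon response genes. Camera did not call Wnt/beta-catenin target genes (adjusted p = 0.615), while fry, which does not compare a list with other genes, gave an adjusted p of 0.00850 for a rise with a median of 0.07 (over 19 alternatives 0.00850 to 0.976). In all, 3357 genes rose and 2594 fell, of which 1287 changed at least 1.5-fold and 339 at least 2-fold. The siTAZ and control arrays did not overlap for 29.6% of genes, against 2.86% by chance.

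Among the largest measured increases in siTAZ cells were those in VAT1L (log2 change 3.28, 9.70-fold, adjusted p = 5.07e-12), GNG2, a G protein subunit (2.87), PLPPR4 (2.77), SAMD9, an interferon-responsive gene (2.69), KANK4 (2.29), the steroid-metabolising enzyme gene AKR1C3 (2.28), the cytokine gene IL24 (2.28) and PWWP3B (2.13). Besides WWTR1 itself, HMGA2, an architectural chromatin protein, fell by 2.92 (SE 0.05, 7.58-fold, adjusted p = 4.91e-16). Other large decreases were in DDAH1, an enzyme that degrades methylated arginine (-2.78), the tetraspanin gene TSPAN6 (-2.69), MPC2, a subunit of the mitochondrial pyruvate carrier (-2.63), CCN2, the methionine metabolism gene MAT2B (-2.39) and the cell-cycle transcription factor gene E2F8 (-2.39). The control means of PLPPR4, SAMD9, KANK4, AKR1C3 and PWWP3B also lay below 5.10, so the sizes and order of their changes are uncertain.

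Among the YAP/TAZ target genes in siTAZ cells, 3 rose, 12 fell and 10 did not pass the test (5 rose and 12 fell when adjusted over the list alone), with a median change of -0.24. Camera gave an adjusted p of 1.80e-04, and the adjusted p = 0.0597 with an estimated correlation. Besides CCN2, those that fell included CRIM1 (-1.05), CCN1, a secreted protein of the same family as CCN2 (-0.97), and NT5E (-0.93). Of 27 Wnt/beta-catenin target genes, 9 rose and 4 fell (the same counts adjusted over the list alone), with a median difference of 0.07. The Notch ligand gene JAG1 rose by 1.22 and EPHB3 by 0.51, while FGF18 fell by 0.63 and CDC25A by 0.44.

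Camera called 2 cell-cycle lists and the ribosome biogenesis list lower in siTAZ cells, and 0 of these 3 calls held with an estimated correlation. Of 30 DNA replication and G1/S genes 2 rose and 16 fell (2 and 16 adjusted over the list alone; median -0.18, camera adjusted p = 3.33e-04, adjusted p = 0.117 with an estimated correlation). UHRF1 (-0.78), the replication clamp gene PCNA (-0.66) and TYMS (-0.65) were among them. Of 31 mitosis and G2/M genes 0 rose and 13 fell (0 and 13 adjusted over the list alone; median -0.14, camera adjusted p = 6.46e-04, adjusted p = 0.0727 with an estimated correlation). The centromere histone gene CENPA (-0.90), CDK1 (-0.62) and MAD2L1 (-0.51) changed most. Ribosome biogenesis genes of the MYC programme, of which 2 rose and 7 fell of 25 (2 and 9 adjusted over the list alone), had a camera adjusted p of 0.0124 and an adjusted p = 0.123 with an estimated correlation; ODC1 (-0.76), NIP7 (-0.53) and CAD (-0.38) changed most. MAD2L1 and NIP7 did not pass the test in replicates A and B alone or with the ACTB measure of RNA quality as a covariate, and NIP7 (-0.40) did not pass it without control replicate C.

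Camera also called 2 metabolic lists and the junction list lower in siTAZ cells, and again 0 of the 3 calls held with an estimated correlation. Of 18 cholesterol biosynthesis genes 1 rose and 9 fell (1 and 9 adjusted over the list alone; camera adjusted p = 0.0111, adjusted p = 0.117 with an estimated correlation). The epoxidase gene SQLE (-1.08), INSIG1 (-0.55) and IDI1 (-0.46) were among them. Of 24 oxidative phosphorylation genes 2 rose and 9 fell (2 and 11 adjusted over the list alone; camera adjusted p = 0.00358, adjusted p = 0.0597 with an estimated correlation). NDUFB5 (-1.01), COX5A (-0.32) and CYC1 (-0.29) changed most. Of 26 epithelial junction and keratin genes 4 rose and 10 fell (4 and 11 adjusted over the list alone; camera adjusted p = 0.047, adjusted p = 0.274 with an estimated correlation): the E-cadherin gene CDH1 fell by 1.13 and TJP1 by 0.76, while CLDN1 rose by 0.90. Beside these lists, the difference between 3' and 5' ACTB probe sets, a sign of RNA quality or labelling, was 2.57 ± 0.39 in siTAZ and 2.05 ± 0.16 in control cells (exact two-sided permutation p = 0.0571), and with it as a covariate the cholesterol and junction lists no longer passed camera. Their medians went from -0.14 to -0.11 and from -0.12 to -0.07. The junction list also did not pass with the replicate block (adjusted p = 0.0786) or with A and B against C and D as a block (0.0774), and passed in 6 of 19 alternatives. Over 19 alternatives their adjusted p ran from 2.75e-06 to 0.117 and from 6.12e-05 to 0.274.

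Of 3 lists that camera called higher in siTAZ cells, only the interferon response list held with an estimated correlation. Of 32 interferon response genes 15 rose and 2 fell (16 and 2 adjusted over the list alone; median 0.17, camera adjusted p = 0.00124, adjusted p = 0.00975 with an estimated correlation). ISG20 (1.05), the antiviral genes TRIM22 (1.00) and MX2 (0.85) were among them, with TRIM22 below 5.10 in both groups. Of 24 NF-kappaB and inflammatory genes 13 rose and 3 fell (13 and 3 adjusted over the list alone; camera adjusted p = 0.00332, adjusted p = 0.0621 with an estimated correlation). The chemokine gene CCL2 (1.31), SOD2 (1.02) and CXCL8 (0.95) changed most. Of 25 immediate early and MAPK feedback genes 12 rose and 3 fell (15 and 4 adjusted over the list alone; camera adjusted p = 0.0206, adjusted p = 0.241 with an estimated correlation). The phosphatase gene DUSP5 (1.31), FOSL1 (0.65) and SPRY4 (0.60) were among them. Without probe sets that can cross-hybridise, the NF-kappaB and immediate early lists no longer passed camera, with adjusted p over 19 alternatives of up to 0.695 and 0.241. The NF-kappaB median went from 0.21 to 0.12 and the immediate early median from 0.21 to 0.22. Camera did not call Hippo pathway and TEAD components (9 higher and 3 lower of 23, adjusted p = 0.283), Wnt pathway components (9 and 4 of 30, 0.547), cyclin-dependent kinase inhibitors and p53 targets (11 and 4 of 20, 0.0662), glycolysis and hypoxia response genes (10 and 4 of 24, 0.183) or unfolded protein and amino acid stress response genes (5 and 11 of 24, 0.0725).

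The siRNA against beta-catenin lowered Wnt target genes and nearly every cell-cycle and ribosome biogenesis gene examined. It raised extracellular matrix, glycolysis and interferon response genes. Of 27 Wnt/beta-catenin target genes 21 fell and 3 rose, led by FGF20, which fell by 3.10 (SE 0.08, n = 4 per group, adjusted p = 1.96e-14). YAP/TAZ target genes went both ways. In all, 3683 genes rose and 3416 fell, of which 1969 changed at least 1.5-fold and 604 at least 2-fold. For 33.5% of genes the sibcat and control arrays did not overlap.

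Among the largest measured increases in sibcat cells were those in the engulfment receptor gene MEGF10 (log2 change 3.52, adjusted p = 1.41e-12), the chemokine gene CCL7 (3.29), SPARC, a matrix-associated protein (3.27), TMT1A (3.23), the netrin gene NTN4 (3.20), COXFA4L3 (3.12), the cholesterol exporter gene ABCA1 (2.94) and LAPTM5 (2.75). TMT1A rested on a probe set that can cross-hybridise, and without such probe sets its difference was -0.03. Large decreases were in MUCL1 (-4.29, SE 0.12, 19.6-fold, adjusted p = 1.97e-13), OLR1, a receptor for oxidised lipoprotein (-4.21), the hyaluronan-binding protein gene CEMIP (-3.82), STMN1, a microtubule regulator (-3.56), the kinase gene HUNK (-3.42), the histone variant gene H2AZ1 (-3.24), TMEM52B (-3.15) and DCLK1 (-3.11). STMN1 also rested on such a probe set, and without it the difference was -0.28. The means of MEGF10, NTN4, COXFA4L3 and ABCA1 in control cells and of OLR1 and TMEM52B in sibcat cells lay below 5.10, so the sizes and order of their changes are uncertain.

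The Wnt/beta-catenin target genes had a median change of -1.09 in sibcat cells (3 higher and 21 lower also when adjusted over the list alone; camera adjusted p = 1.72e-12, adjusted p = 0.00258 with an estimated correlation). Besides FGF20, the receptor gene TNFRSF19 (-2.64), the transcription factor gene SP5 (-2.28) and NKD1, a feedback inhibitor of Wnt signalling (-2.17), fell most. Of 14 intestinal stem cell markers 6 fell and 1 rose (6 and 2 adjusted over the list alone; median -0.02, camera adjusted p = 0.0206, adjusted p = 0.0621 with an estimated correlation). The median was 0.04 without control replicate B and 0.02 in C and D alone, where the call was lost (adjusted p = 0.0749; over 19 alternatives 2.25e-11 to 0.0749). TNFRSF19, the Wnt feedback gene AXIN2 (-1.66) and ASCL2 (-1.54) changed most. All of these are also in the Wnt/beta-catenin target list, so the stem cell call is not separate from the Wnt target call. Of 30 Wnt pathway components 14 rose and 3 fell (14 and 3 adjusted over the list alone; camera adjusted p = 0.0206, adjusted p = 0.169 with an estimated correlation). FZD1 (1.08) and BCL9L (0.84) were higher and CSNK1A1 (-0.99) was lower; CSNK1A1 is uncertain, since of its 12 other probe sets 4 moved the same way past the threshold and 2 the opposite way. Of 25 YAP/TAZ target genes 12 rose and 5 fell (12 and 6 adjusted over the list alone), with a median difference of 0.15 and a camera adjusted p of 0.134. CCN2, with a sibcat mean of 5.08, below 5.10, fell by 2.18 and CRIM1 by 1.24, while NT5E rose by 1.49 and TGFB2 by 0.99.

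Camera called the replication, mitosis, ribosome biogenesis and unfolded protein lists lower in sibcat cells, and all but the unfolded protein list held with an estimated correlation. Of 30 DNA replication and G1/S genes 0 rose and 29 fell (0 and 29 adjusted over the list alone; median -0.55, camera adjusted p = 1.88e-16, adjusted p = 0.00258 with an estimated correlation). The replication factor genes GINS1 (-1.38), MCM10 (-1.20) and CDC6 (-0.85) were among them. Of 31 mitosis and G2/M genes 0 rose and 27 fell (0 and 28 adjusted over the list alone; median -0.43, camera adjusted p = 8.91e-12, adjusted p = 0.00258 with an estimated correlation). The checkpoint gene MAD2L1 (-0.90), CCNB1 (-0.67) and KIF11 (-0.66) changed most. Of 25 ribosome biogenesis genes of the MYC programme 0 rose and 22 fell (1 and 22 adjusted over the list alone; median -0.51, camera adjusted p = 8.61e-11, adjusted p = 0.00258 with an estimated correlation). ODC1 (-1.23), NIP7 (-0.68) and WDR43 (-0.66) were among them. Of 24 unfolded protein and amino acid stress response genes 5 rose and 11 fell (5 and 11 adjusted over the list alone; camera adjusted p = 0.0249, adjusted p = 0.117 with an estimated correlation). The asparagine synthetase gene ASNS (-1.48), the cystine transporter gene SLC7A11 (-1.34) and PSAT1 (-0.91) changed most. The ASNS change rested on a probe set that can cross-hybridise, and its other probe set gave -0.11.

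Camera called the matrix, mesenchymal, glycolysis, interferon and apoptosis lists higher in sibcat cells, and all but the apoptosis list held with an estimated correlation. Of 23 extracellular matrix and secreted protease genes 12 rose and 0 fell (12 and 0 adjusted over the list alone; median 0.37, camera adjusted p = 1.56e-05, adjusted p = 0.00258 with an estimated correlation). The urokinase gene PLAU (2.64), the protease inhibitor gene TIMP3 (2.02) and MMP9 (1.76) were among them. Of 22 mesenchymal genes 8 rose and 2 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.00892, adjusted p = 0.0362 with an estimated correlation). SPARC and the transcription factor genes SNAI2 (1.68) and ZEB1 (1.33) changed most. Of 24 glycolysis and hypoxia response genes 20 rose and 1 fell (20 and 1 adjusted over the list alone; median 0.28, camera adjusted p = 9.98e-06, adjusted p = 0.00258 with an estimated correlation). DDIT4 (0.95) and VEGFA (0.62) were higher and ANKRD37 (-0.71) was lower. Of 32 interferon response genes 21 rose and 6 fell (21 and 7 adjusted over the list alone; median 0.48, camera adjusted p = 6.38e-05, adjusted p = 0.00258 with an estimated correlation). TRIM22 (2.73, with a control mean below 5.10), IFIT1 (2.01) and IFI35 (1.44) were among them. Of 22 apoptosis and survival genes 12 rose and 4 fell (12 and 4 adjusted over the list alone; camera adjusted p = 0.016, adjusted p = 0.0597 with an estimated correlation). The death ligand gene TNFSF10 (2.01), BMF (1.07) and BCL2L11 (0.83) changed most. Without probe sets that can cross-hybridise, the glycolysis, Wnt pathway and unfolded protein lists no longer passed camera. Over 19 alternatives their adjusted p reached 0.119, 0.283 and 0.117. The Wnt pathway median went from 0.18 to 0.03 and the glycolysis median from 0.28 to 0.23, and the unfolded protein median was -0.14 in both. Camera did not call Hippo pathway and TEAD components in sibcat cells (7 higher and 5 lower of 23, adjusted p = 0.834), nor NF-kappaB and inflammatory genes (8 and 5 of 24, 0.334) or cholesterol biosynthesis genes (4 and 6 of 18, 0.714).

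In APC cells the Wnt target list and the YAP/TAZ target list were lower than in control cells, as were cholesterol, hypoxia and stress response genes, and several MHC class II genes were higher. The labels do not say whether the APC arrays come from 1 stable line or several, so differences of a line are not separated from those of APC. The Wnt antagonist gene DKK4, itself a Wnt target, rose by 6.50 (SE 0.12, 90.2-fold, n = 4 per group, adjusted p = 2.88e-16) against the direction of its list. In all, 3290 genes rose and 3380 fell, of which 1868 changed at least 1.5-fold and 792 at least 2-fold. For 31.7% of genes the APC and control arrays did not overlap.

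Besides DKK4, large measured increases in APC cells were in the MHC class II genes HLA-DPA1 (6.49, SE 0.09, adjusted p = 1.57e-17) and HLA-DRA (6.27), the Paneth cell defensin gene DEFA5 (5.08), DNER (4.97), HLA-DRB1 (4.55), the non-coding RNA gene AFAP1-AS1 (4.29) and HLA-DPB1 (4.23). Large decreases were in TMEM47 (-5.49, SE 0.09, 45.0-fold, adjusted p = 4.74e-17), CTHRC1, a secreted collagen-associated protein (-4.90), the exocytosis gene CADPS (-4.65), the neurotrophin receptor gene NTRK2 (-4.64), FGF13 (-4.46), OLR1 (-4.46), ADGRG2 (-4.41) and the troponin gene TNNC1 (-4.15). HLA-DPA1 went from a mean of 4.37 in control cells to 10.86. Apart from DKK4, HLA-DRB1, TMEM47 and CTHRC1, the means of these genes lay below 5.10 in control cells for the increases or in APC cells for the decreases, so the sizes and order of these changes are uncertain.

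Of 27 Wnt/beta-catenin target genes 2 rose and 20 fell in APC cells (2 and 21 adjusted over the list alone; median -0.68, camera adjusted p = 5.71e-11, adjusted p = 0.00258 with an estimated correlation). The Wnt antagonist gene DKK1 (-2.96), TNFRSF19 (-2.08) and FGF18 (-1.79) were among them. Of 25 YAP/TAZ target genes 4 rose and 15 fell (4 and 15 adjusted over the list alone; median -0.46, camera adjusted p = 1.55e-06, adjusted p = 0.0194 with an estimated correlation). CCN2 (-3.49, with an APC mean of 3.77, below 5.10), IGFBP3 (-2.59), ANKRD1 (-2.32) and AJUBA (-2.23) were among them. Of 23 Hippo pathway and TEAD components 2 rose and 10 fell (3 and 10 adjusted over the list alone; camera adjusted p = 0.00802, adjusted p = 0.117 with an estimated correlation), including AMOTL2 (-1.86), the kinase gene LATS2 (-1.27) and FAT1 (-0.90); AMOTL2 and LATS2 are also in the YAP/TAZ target list. Camera did not call Wnt pathway components (8 higher and 4 lower of 30, adjusted p = 0.396).

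**Figure D2:**
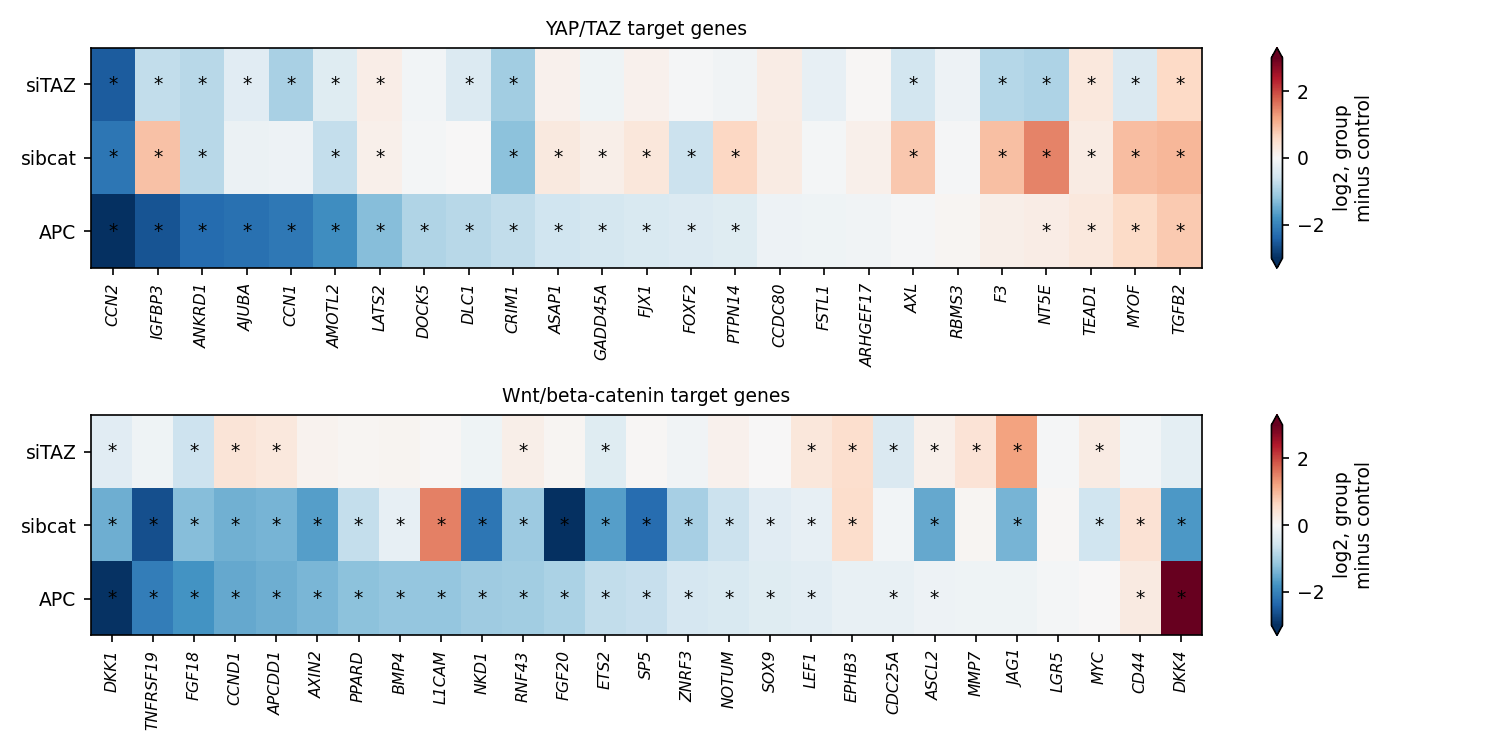
Log2 change from control of each YAP/TAZ target gene (25 genes) and each Wnt/beta-catenin target gene (27 genes) in siTAZ, sibcat and APC cells (n = 4 per group), ordered by the change in APC cells; an asterisk marks an adjusted p under 0.05 and colours saturate at the ends of the bar. CCN2 is lower in all 3 groups, and most Wnt/beta-catenin target genes are lower in sibcat and APC cells, with DKK4 higher in APC cells.

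Camera called 5 further lists lower in APC cells, of which the cholesterol, glycolysis and unfolded protein lists held with an estimated correlation. Of 18 cholesterol biosynthesis genes 1 rose and 11 fell (1 and 11 adjusted over the list alone; median -0.53, camera adjusted p = 1.18e-05, adjusted p = 0.0167 with an estimated correlation). The sterol transport gene STARD4 (-1.84), INSIG1 (-1.42) and MSMO1 (-1.16) were among them. Of 24 glycolysis and hypoxia response genes 1 rose and 13 fell (1 and 15 adjusted over the list alone; median -0.15, camera adjusted p = 1.09e-05, adjusted p = 0.00258 with an estimated correlation). ANKRD37 (-1.18) and the hypoxia-induced genes NDRG1 (-2.24) and EGLN3 (-1.96) changed most. ANKRD37 is uncertain, since another probe set of it moved the opposite way past the threshold. Of 24 unfolded protein and amino acid stress response genes 4 rose and 17 fell (4 and 18 adjusted over the list alone; median -0.51, camera adjusted p = 5.07e-06, adjusted p = 0.00391 with an estimated correlation). VLDLR (-1.92) and the stress transcription factor genes DDIT3 (-1.61) and ATF3 (-1.35) were among them. Of 25 immediate early and MAPK feedback genes 4 rose and 14 fell (4 and 16 adjusted over the list alone; camera adjusted p = 0.00183, adjusted p = 0.117 with an estimated correlation). FOS (-2.40), EGR3 (-2.39) and FOSL2 (-1.52) changed most. Of 20 cyclin-dependent kinase inhibitors and p53 targets 2 rose and 9 fell (2 and 9 adjusted over the list alone; camera adjusted p = 0.0371, adjusted p = 0.241 with an estimated correlation). CDKN1C (-1.27) and RRM2B (-0.79) were lower and CDKN2B (1.11) was higher.

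Of 5 lists that camera called higher in APC cells, only the interferon response list held with an estimated correlation. Of 30 DNA replication and G1/S genes 15 rose and 2 fell (15 and 2 adjusted over the list alone; median 0.15, camera adjusted p = 8.83e-04, adjusted p = 0.136 with an estimated correlation), with the thymidine kinase gene TK1 (0.88) and GINS2 (0.79) higher and CCNE2 (-0.63) lower; GINS2 differed by 0.12 without probe sets that can cross-hybridise and did not pass the test there. Of 25 ribosome biogenesis genes of the MYC programme 11 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 0.00702, adjusted p = 0.117 with an estimated correlation). POLR1A (0.71), NOLC1 (0.37) and FBL (0.36) were among them. Of 24 oxidative phosphorylation genes 11 rose and 2 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.0249, adjusted p = 0.119 with an estimated correlation). CYC1 (0.34) and NDUFS3 (0.33) were higher and UQCRC1 (-0.32) was lower. Of 32 interferon response genes 18 rose and 8 fell (19 and 8 adjusted over the list alone; median 0.40, camera adjusted p = 0.0141, adjusted p = 0.0385 with an estimated correlation). The chemokine genes CXCL10 (1.5) and CXCL11 (1.32) and IFIT3 (1.46) were among them, with CXCL10 below 5.10 in control cells and CXCL11 below it in both groups. Of 24 NF-kappaB and inflammatory genes 12 rose and 5 fell (12 and 5 adjusted over the list alone; camera adjusted p = 0.016, adjusted p = 0.117 with an estimated correlation). CCL2 (2.89), the cyclooxygenase gene PTGS2 (1.77) and LCN2 (1.74) were among them, with PTGS2 below 5.10 in both groups. Without probe sets that can cross-hybridise, the p53, respiratory, interferon, NF-kappaB and immediate early lists no longer passed camera in APC cells. Over 19 alternatives their adjusted p reached 0.293, 0.119, 0.160, 0.117 and 0.117. The medians without these probe sets were -0.09, 0.13, 0.40, 0.13 and -0.15, against -0.08, 0.10, 0.40, 0.19 and -0.22 with them. Mitosis and G2/M genes were not called in APC cells (7 higher and 6 lower of 31, adjusted p = 0.468).

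**Figure D3:**
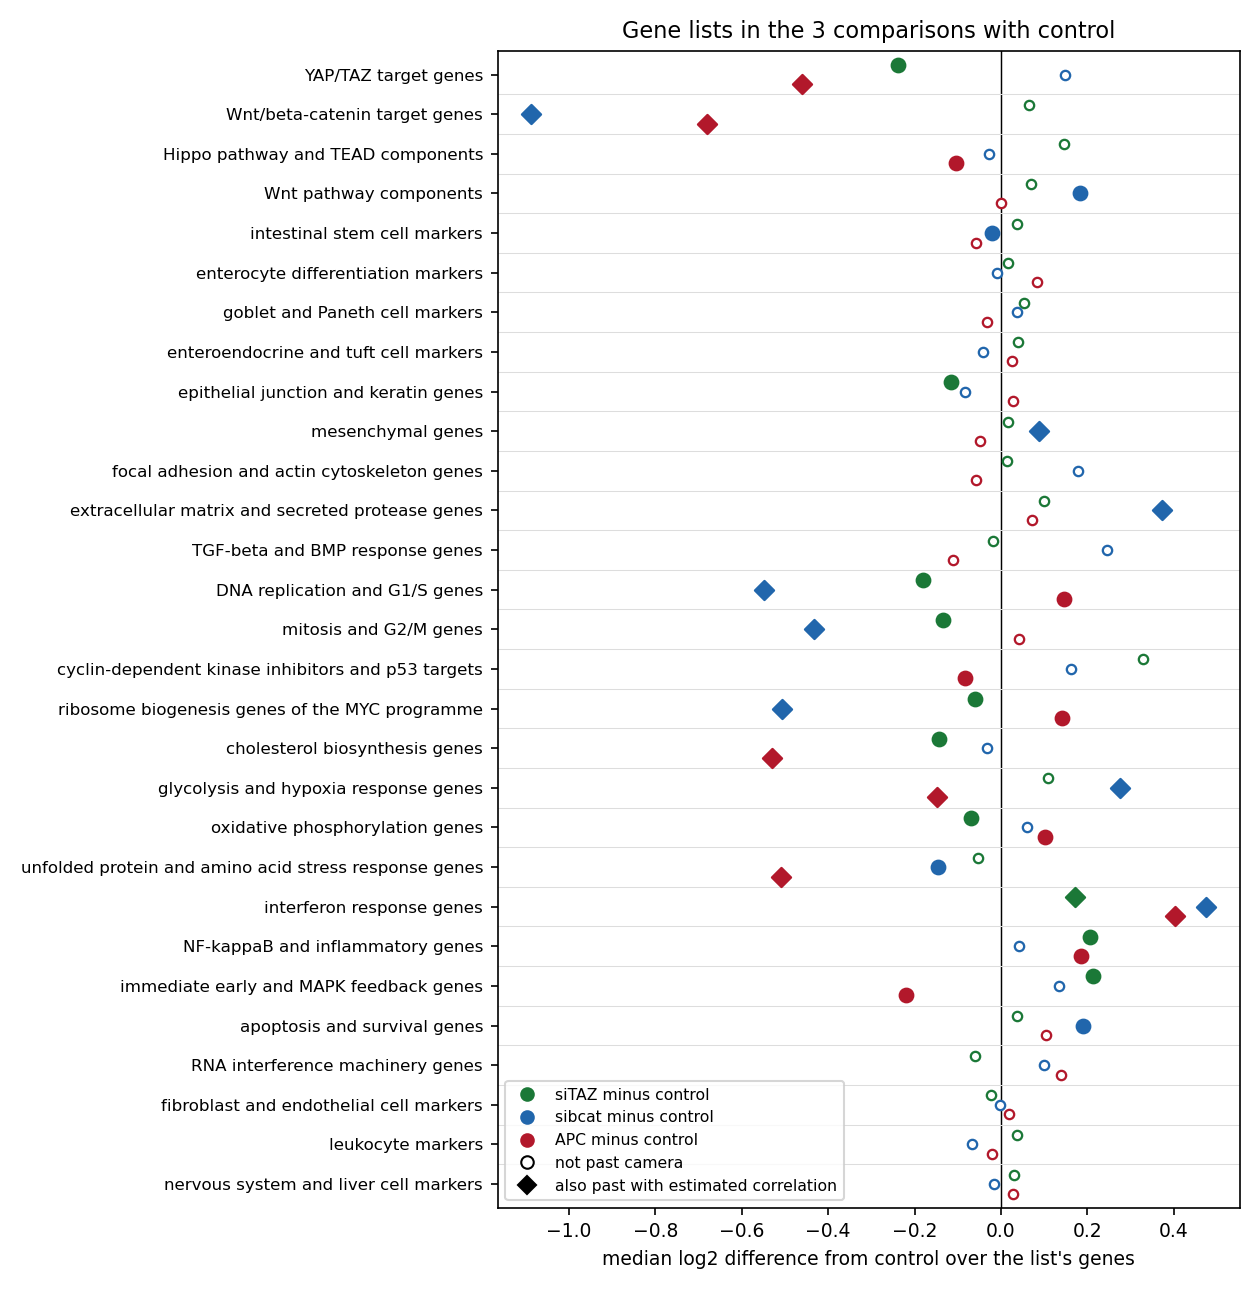
Median log2 difference from control over each of the 29 gene lists in siTAZ, sibcat and APC cells. Filled symbols passed camera and diamonds also passed with an estimated correlation; the Wnt/beta-catenin target list lies at -1.09 in sibcat and -0.68 in APC cells, and the DNA replication list at -0.55 in sibcat and 0.15 in APC cells.

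Camera called 35 of the 87 list tests, 10 in siTAZ, 12 in sibcat and 13 in APC cells, and 15 of these held with an estimated correlation. Markers of other lineages and several further lists passed camera in 0 of the 3 comparisons. For markers of fibroblasts and endothelium the adjusted p was 0.831 in siTAZ, 0.863 in sibcat and 0.988 in APC cells, with 0, 1 and 2 of 16 genes changed; for leukocyte markers it was 0.583, 0.840 and 0.834, with 3 of 13 genes changed in each. Nervous system and liver markers had 0.328, 0.863 and 0.882. The enterocyte differentiation markers had adjusted p-values of 0.893, 0.714 and 0.205, the goblet and Paneth cell markers 0.880, 0.834 and 0.712, and the enteroendocrine and tuft cell markers 0.834, 0.574 and 0.900. Focal adhesion and actin cytoskeleton genes had 0.491, 0.0662 and 0.444, TGF-beta and BMP response genes 0.840, 0.687 and 0.271, and RNA interference machinery genes 0.863, 0.878 and 0.834. Median, mean and test differed in sign only among lists that were not called, namely focal adhesion and RNA interference genes in siTAZ cells, enterocyte and leukocyte markers in sibcat cells, and goblet and Paneth, enteroendocrine and tuft, leukocyte, and nervous system and liver markers in APC cells.

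Compared directly, siTAZ cells had higher Wnt/beta-catenin target and growth genes than sibcat cells, and lower extracellular matrix genes. YAP/TAZ target genes were also called lower, a call that was lost with an estimated correlation (adjusted p = 0.0523 with an estimated correlation). In siTAZ relative to sibcat cells 3737 genes were higher and 3522 lower, of which 2280 differed at least 1.5-fold and 878 at least 2-fold. MUCL1 (5.25), TMEM52B (4.75), OLR1 (4.51) and PLPPR4 (4.10) were among the genes higher in siTAZ cells, and HMGA2 (-4.37), WWTR1 (-4.07), DDAH1 (-3.53) and the integrin gene ITGB8 (-3.09) among those lower. The sibcat means of TMEM52B, OLR1 and PLPPR4 lay below 5.10, so the sizes of these differences are uncertain. YAP1 was higher by 1.16 (adjusted p = 6.28e-09). Of the Wnt/beta-catenin target genes 22 of 27 were higher in siTAZ cells and 3 lower (median 0.89, camera adjusted p = 2.21e-12 over 58 tests, adjusted p = 0.00106 with an estimated correlation). Of the YAP/TAZ target genes 3 of 25 were higher and 12 lower (median -0.19, camera adjusted p = 3.54e-04). DNA replication and G1/S genes were higher in siTAZ cells (23 higher and 1 lower of 30, camera adjusted p = 5.48e-08, adjusted p = 0.0264 with an estimated correlation), as were ribosome biogenesis genes (21 and 0 of 25, 4.25e-07, adjusted p = 0.00854 with an estimated correlation). Extracellular matrix genes were lower (2 higher and 11 lower of 23, camera adjusted p = 0.00146, adjusted p = 0.0130 with an estimated correlation).

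Against sibcat cells, APC cells had lower YAP/TAZ target genes and higher growth genes. In APC relative to sibcat cells 4011 genes were higher and 4297 lower, of which 2823 differed at least 1.5-fold and 1014 at least 2-fold. DKK4 (8.21), HLA-DPA1 (5.88), HLA-DRA (5.64) and DEFA5 (5.50) were among the genes higher in APC cells, and CTHRC1 (-4.66), the NAD synthesis gene QPRT (-4.00), the keratin gene KRT13 (-3.80) and SPARC (-3.74) among those lower. The means of DKK4, HLA-DPA1 and DEFA5 in sibcat cells and of KRT13 in APC cells lay below 5.10, so the sizes and order of these differences are uncertain. Of 25 YAP/TAZ target genes 2 were higher and 19 lower (median -0.84, camera adjusted p = 1.31e-08, adjusted p = 0.00854 with an estimated correlation), while WWTR1 itself differed by 0.03 (adjusted p = 0.811) and YAP1 was higher by 0.56 (adjusted p = 2.57e-05). Of 30 DNA replication and G1/S genes 29 were higher and 0 lower (median 0.69, camera adjusted p = 1.84e-16, adjusted p = 0.00395 with an estimated correlation), and 25 of 25 ribosome biogenesis genes were higher (median 0.63, camera adjusted p = 1.60e-12, adjusted p = 0.00149 with an estimated correlation). Of 24 glycolysis and hypoxia response genes 0 were higher and 22 lower (median -0.52, camera adjusted p = 4.19e-12, adjusted p = 2.87e-04 with an estimated correlation). Wnt/beta-catenin target genes did not differ as a list (11 higher and 7 lower of 27, camera adjusted p = 0.292).

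Genes changed in the same direction and in opposite directions were counted for each pair of comparisons. CCN2 was among the 357 genes that fell in all 3 groups, and 632 genes rose in all 3. Genes lower in both siTAZ and sibcat cells numbered 1205 and genes higher in both 1556, against 448 and 625 from the product of the counts; 454 were lower in siTAZ and higher in sibcat cells and 596 the reverse, against 483 and 580. Besides CCN2, large falls in both were in TMEM30B (-1.79 and -1.53), SIRT1 (-1.61 and -1.25), EAF1 (-1.52 and -1.34) and PIP5K1B (-1.5 and -1.69), and large rises in AKR1C3 (2.28 and 2.27), SAMD9 (2.69 and 1.93), TMT1A (1.73 and 3.23), HSD3B1 (1.69 and 2.75) and ENPP5 (1.78 and 1.66); PIP5K1B and TMT1A in siTAZ cells did not pass the test without probe sets that can cross-hybridise. APC and sibcat cells had 1187 genes lower in both and 1349 higher in both, against 584 and 613, with 820 and 634 in opposite directions, against 630 and 568. OLR1, TMEM52B (-4.04 and -3.15), ADAMTS8 (-3.25 and -3.08), ANO4 (-3.35 and -2.71) and LINC01992 (-2.56 and -2.99) were among those that fell in both, and MEGF10 (3.52 in each), NTN4 (4.00 and 3.20), ABCA1 (3.30 and 2.94), CCL2 (2.89 and 2.74) and the leukotriene synthesis gene ALOX5AP (4.22 and 2.71) among those that rose. Of the 1187 genes lower in both sibcat and APC cells, 357 also fell in siTAZ cells, 319 rose and 511 did not pass the test. The means of CCN2, OLR1, TMEM52B, ANO4 and LINC01992 in the lowered groups and of AKR1C3, SAMD9, HSD3B1, MEGF10, NTN4 and ABCA1 in control cells lay below 5.10, so the sizes of these changes are uncertain.

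The pair of siTAZ and APC cells had nearly as many opposite as shared changes, with 1699 genes in the same direction and 1697 in opposite directions. It had 711 genes lower in both and 988 higher in both, against 443 and 559, and 644 and 1053 in opposite directions, against 432 and 574. CCN2, the histone genes H2BC4 (-2.15 and -2.0), H2BC12L (-1.79 and -2.20) and H2BC12 (-1.61 and -2.14), and MAMDC2 (-1.92 and -2.37) were among those that fell in both, and SAMD9 (2.69 and 3.18), the chemokine gene CXCL6 (1.98 and 2.42), SERPINI1 (1.60 and 1.72), the transporter gene ABCG1 (1.55 and 1.85) and the epithelial transcription factor gene EHF (1.53 and 3.44) among those that rose; ABCG1 in siTAZ cells did not pass the test without probe sets that can cross-hybridise. The means of H2BC4 in both groups lay below 5.10, and those of MAMDC2 also in control cells. Because all 3 comparisons used the same control arrays, noise in the controls alone makes changes correlate. Across genes, which are not independent replicates, the correlation was 0.234 for siTAZ and sibcat, 0.335 for APC and sibcat and 0.0353 for siTAZ and APC, where unchanged groups against shared controls gave 0.498, 0.498 and 0.499. The covariances were 0.0297, 0.0617 and 0.00518, against simulated covariances of 0.00480, 0.00480 and 0.00481. The same simulations gave 0 genes called in the same direction in both comparisons. They held no changed genes, so this 0 follows from their design. Their correlations and counts set no level for groups in which many genes changed. Their covariances show what noise in the shared controls adds. With the controls split so that each comparison used its own 2 arrays, the correlations ran from 0.157 to 0.193, from 0.275 to 0.313 and from -0.0261 to 0.0134, the covariances from 0.0211 to 0.0253, from 0.0529 to 0.0586 and from -0.00407 to 0.00202, and the shared genes from 1933 to 2100, from 1888 to 2024 and from 1125 to 1245. The median numbers of genes in opposite directions under these splits were 771, 1077 and 1256.5, so for siTAZ and APC it lay above the whole range of shared genes.

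**Figure D4:**
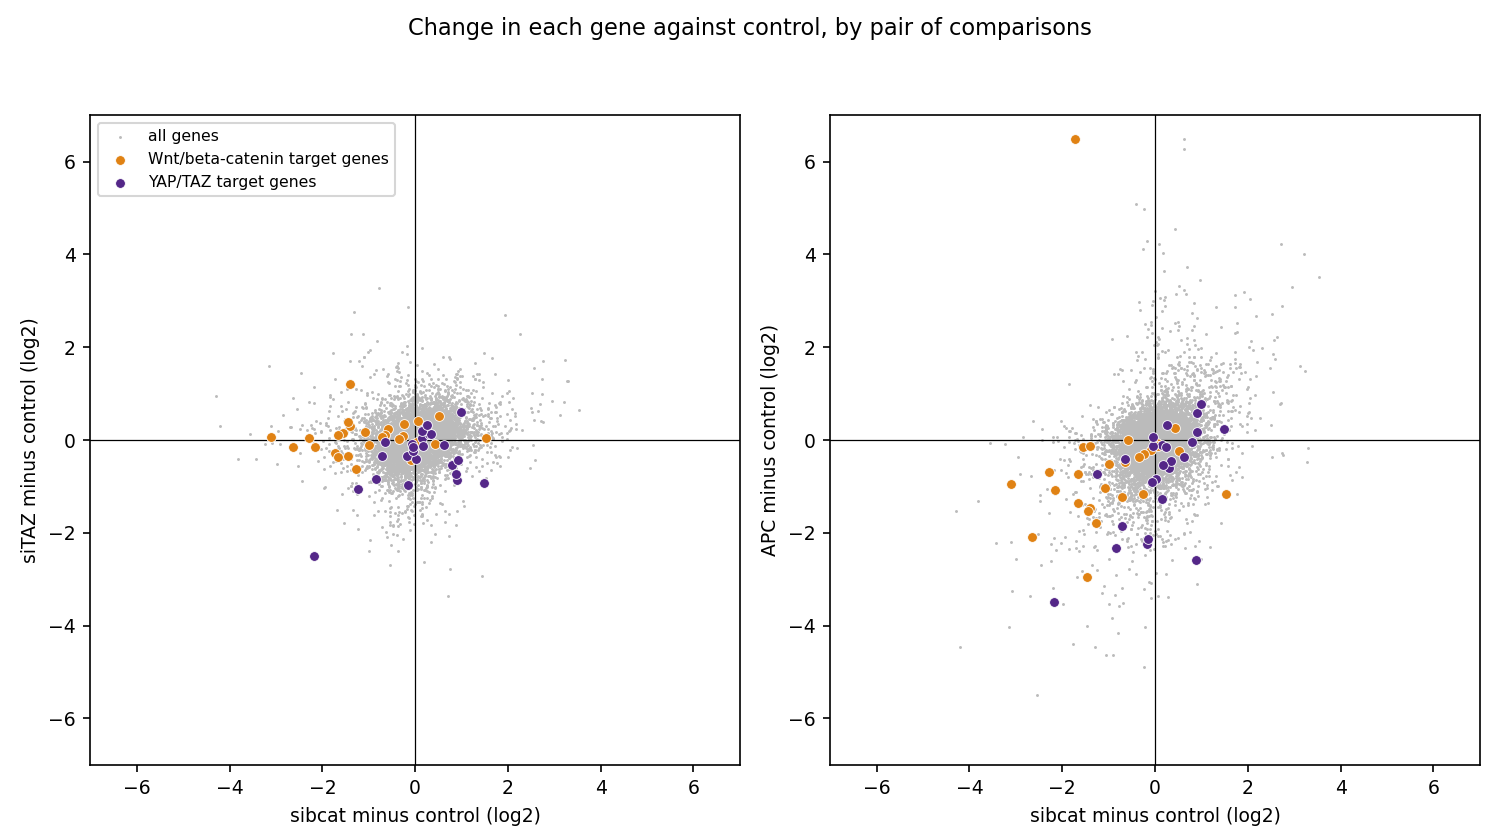
Log2 change from control of each of the 19775 genes in sibcat cells (horizontal) against siTAZ cells (left) and APC cells (right), with the 27 Wnt/beta-catenin target genes and the 25 YAP/TAZ target genes in colour. The correlation across genes is 0.234 on the left and 0.335 on the right, and DKK4 stands alone at 6.50 in APC cells among the Wnt/beta-catenin target genes.

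Between groups, arrays A and B deviated from their group means alike, and opposite to arrays C and D. After subtracting group means, pairs of arrays from different groups were correlated across genes. Pairs from the same set (A and B, or C and D) correlated above 0 in 48 of 48 cases, and pairs from different sets below 0 in 48 of 48. The separation was not complete within the controls. There, array A differed less from C and D (SD of the difference 0.208 and 0.210) than from B (0.246). Between the sets 3797 genes differed, 18 of them at least 1.5-fold, with 0 gene lists past camera. The ACTB difference was higher in A and B (2.47 ± 0.30, n = 8) than in C and D (2.03 ± 0.19), in 4 of 4 groups (exact two-sided permutation p within groups = 0.00154). Arrays with the same letter correlated at 0.0843 to 0.403, with 22 of 24 pairs above 0.1, which fell short of the rule for treating letters as pairs. In A and B alone 3566, 4827 and 4183 genes changed in siTAZ, sibcat and APC cells, 5142 differed between siTAZ and sibcat and 6360 between APC and sibcat cells; in C and D alone the counts were 5287, 6298, 5866, 6528 and 7489. With the 2 sets as a block the counts were 6894, 7961, 7722, 8100 and 9080.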

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

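Of the tests below, those on the YAP/TAZ target genes and on the DNA replication genes were chosen after the results had been seen, as were the splits with a block, and those on the arrays A and B against C and D and on the remaining splits of the arrays before. Among 467 groups of 4 values (named genes and the mean levels of gene lists), 24 held an array whose gap to the nearest other array exceeded Dixon's critical value for 4 samples; chance gives about 1 in 20 groups, or 23.4. All values below are log2 levels, with the range of the other 3 arrays of the group beside each.

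Among control arrays, A was apart in CYC1 (10.52 against 10.32 to 10.35), MUCL1 (9.67 against 9.73 to 9.74), TK1 (9.09 against 8.97 to 8.98) and the mean of the oxidative phosphorylation genes (11.39 against 11.37). Control array B was apart in CXCL11 (3.25 against 3.87 to 3.94), E2F8 (7.92 against 8.44 to 8.53), PLPPR4 (4.27 against 4.53 to 4.55) and TMEM30B (7.16 against 7.43 to 7.48). Control array D was apart in DDIT3 (8.45 against 8.69 to 8.70) and LATS2 (9.88 against 9.71 to 9.73).

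Among siTAZ arrays, A was apart in NIP7 (8.64 against 8.65), TYMS (11.75 against 11.81 to 11.82) and YAP1 (11.35 against 11.12 to 11.15), B in ABCG1 (6.75 against 6.90 to 6.92) and C in PLPPR4 (7.38 against 7.19 to 7.20). Among sibcat arrays, A was apart in TMEM30B (5.52 against 5.93 to 5.99), YAP1 (9.84 against 10.07 to 10.11) and the mean of the mitosis and G2/M genes (9.97 against 10.03 to 10.04), C in COXFA4L3 (8.42 against 8.08 to 8.12) and SAMD9 (5.87 against 5.67 to 5.69), and D in STMN1 (5.95 against 6.59 to 6.67). Among APC arrays, B was apart in the mean of the YAP/TAZ target genes (8.07 against 8.12 to 8.13), and C in SAMD9 (7.07 against 6.95 to 6.96) and SERPINI1 (7.81 against 7.57 to 7.60).

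YAP/TAZ target genes were lower in APC and siTAZ cells than in control cells but not in sibcat cells, and the direct comparisons with sibcat cells passed camera. With an estimated correlation the siTAZ part was lost (adjusted p = 0.0597 against control and 0.0523 against sibcat cells) and the APC part held (0.0194 and 0.00854); the first 3 tests below concern APC against sibcat cells. RNA quality as the whole cause was argued against, since with the ACTB 3' to 5' difference as a covariate the median APC minus sibcat difference of the list was -0.87 and still passed camera. Dim or cross-hybridising probe sets were argued against by a median of -0.86 over the 20 bright members without them, and a lower WWTR1 mRNA level in APC than in sibcat cells by a difference of 0.0275 (SE 0.07) between them. A release of TAZ activity on beta-catenin depletion stays open: of the 12 members lowered by siTAZ, 5 were higher and 4 lower in sibcat cells, and members that go both ways decide nothing.

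DNA replication and G1/S genes were lower in sibcat and higher in APC cells than in control cells, though the APC call was lost with an estimated correlation (adjusted p = 0.136), while APC against sibcat held (0.00395). RNA quality as the whole cause was argued against, since with the ACTB covariate the median APC minus sibcat difference was 0.66 and still passed camera. Every group holds 2 arrays of each set, so a constant difference between replicates A and B and replicates C and D cancels in each comparison. The design thus excludes it beforehand. The separate fits show only that the pattern did not rest on 1 set. It was present in 2 of 2 sets (median changes of -0.56 in sibcat and 0.14 in APC cells in A and B, and -0.55 and 0.19 in C and D). MYC mRNA fell by 0.59 in sibcat cells (SE 0.06), so a lower MYC level may explain the sibcat part, while in APC cells it differed by 0.005, which argues against a higher MYC mRNA level there. The stably transfected APC cells and the transient siRNA also differ in time since the change, which remains open.

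Between groups, arrays A and B deviated from their group means opposite to arrays C and D, which splits the arrays on something other than their group. RNA quality or labelling, as read by ACTB, stays open. Across genes, the response to the ACTB difference among arrays of the same set and group correlated at -0.422 with the difference between the sets. This cause needs a positive value (one-sided sign-flip permutation p = 0.996 over 256 flips). The ACTB differences within sets were mostly small beside the mean of 0.45 between the sets, so the test cannot decide. The GAPDH 3' to 5' difference was 0.42 in A and B and 0.31 in C and D (exact two-sided permutation p = 0.0570). This p was taken over all arrays without regard to group, unlike the ACTB p within groups. Both A and B lay above both C and D in control (0.40 and 0.42 against 0.27 and 0.30), sibcat and APC cells. In siTAZ cells the values were 0.65 and 0.47 against 0.40 and 0.50. Control array B alone was argued against, since without it 83.1% of the genes differing between the sets remained. Other differences in handling, such as a shared day, may explain the split and were not tested, and no biological explanation was tested.

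Each comparison of groups was set beside all 35 splits of its 8 arrays into 4 and 4, the real split included. For the genes changed, 1 of 35 splits was as large in each of the 5 comparisons, namely the real one. Against control, siTAZ gave 5951 genes and the highest other split 2, sibcat 7099 and 127, and APC 6670 and 415. Against sibcat, siTAZ gave 7259 and 1, and APC 8308 and 0. A share of 1 of 35 is the smallest that these splits can give. Every other split mixes arrays of both groups, which leaves few genes to call where the groups differ. If the replicates are technical, the splits cannot tell a treatment from a difference between cultures. Gene lists past camera were counted after adjustment over the 29 lists of a comparison. For this count chance cannot be excluded in siTAZ cells (9 lists with this adjustment, highest other split 10, 3 of 35 as large). Nor can it be in sibcat cells (12 lists, highest other split 13, 3 of 35). In APC cells the real split gave the most (13 lists, highest other split 11, 1 of 35), again with the smallest share possible. With A and B against C and D as a block the values were 9 lists against 8 in the highest other split in siTAZ cells (1 of 35), 12 against 13 in sibcat cells (3 of 35) and 13 against 11 in APC cells (1 of 35), so the siTAZ outcome depends on the block. For genes shared in direction, 100 splits of the 12 arrays were drawn, the real one included. The median number of shared genes over the other splits was 0, so that 2 groups with many changes exceed them whether or not their responses are alike, and these splits say nothing on that. The pair siTAZ and sibcat gave 2761 shared genes and the highest other split 2057, with 1 split as large. APC and sibcat gave 2536 and 3850, with 2 splits as large, and siTAZ and APC gave 1699 and 3805, with 2 splits as large. In those last splits with the highest values, all 4 APC arrays or all 4 siTAZ arrays stood in the place of the controls, a structure of the samples that follows the treatments, and the remaining splits gave at most 0.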

How the results depend on the processing

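Settings that separate replicates A and B from C and D, and the ACTB covariate, were chosen after the data had been seen; the other settings before. Over the 5 counts of genes changed, 103 values under other settings stayed within 1.5 times the reported count and 7 were lower. Over the 3 counts of shared genes, 71 stayed within it and 7 were lower. The replicate block, for example, gave 6808 genes in siTAZ, 7898 in sibcat and 7617 in APC cells against control.

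A minimum change of 1.5-fold left 1287 genes in siTAZ, 1969 in sibcat and 1868 in APC cells against control, 2280 between siTAZ and sibcat and 2823 between APC and sibcat cells, and 308, 614 and 207 shared genes for siTAZ and sibcat, APC and sibcat, and siTAZ and APC; a stricter rule passes fewer genes by construction. With only arrays A and B, 3566 genes changed in siTAZ and 4183 in APC cells, with 1420, 1456 and 738 shared genes. The same number of arrays from C and D gave 5287 and 5866 genes, with 2290, 2178 and 1413 shared genes, and the cause of the lower counts in A and B was not tested. An adjusted p under 0.01 left 1092 shared genes for siTAZ and APC, again by construction. Leaving out each array in turn gave 5471 to 6056 genes in siTAZ, 6534 to 7130 in sibcat and 6114 to 6815 in APC cells, 6808 to 6925 between siTAZ and sibcat, and 7842 to 8052 between APC and sibcat cells; the shared genes ran from 2418 to 2890, from 2270 to 2649 and from 1486 to 1822, and the lists past camera from 33 to 36.

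The number of lists past the threshold was 35 with the preset correlation, 15 with an estimated correlation and 69 with fry, which asks a different question. YAP/TAZ target genes in siTAZ cells had a median of -0.24 and an adjusted p = 0.0597 with an estimated correlation (over 19 alternatives 1.02e-08 to 0.0597). With fry, Wnt/beta-catenin target genes in siTAZ cells passed with a median of 0.065 (adjusted p = 0.00850; over 19 alternatives 0.00850 to 0.976), and YAP/TAZ target genes in sibcat cells with a median of 0.15 (7.39e-06; over 19 alternatives 7.39e-06 to 0.409). Of the list results under other settings, 640 kept their side of the threshold, 61 no longer passed and 2 newly passed. Among those 640, direction was compared, and was the same, only where the list passed. Leaving out 1 array ended 4 list calls. Immediate early genes in siTAZ cells had an adjusted p of 0.0924 without control replicate B (over 19 alternatives 2.24e-06 to 0.241). Junction and keratin genes in siTAZ cells had 0.0599 and 0.0804 without control replicates C and D, and 0.0541, 0.0586 and 0.0505 without siTAZ replicates A, B and D, and also did not pass with the replicate block (0.0786) or the block of A and B against C and D (0.0774) (over 19 alternatives 6.12e-05 to 0.274). The p53 list in APC cells had 0.0678 without control replicate D and 0.0572 without APC replicate B (over 19 alternatives 9.79e-06 to 0.293), and oxidative phosphorylation genes in APC cells had 0.0553 without APC replicate C (over 19 alternatives 3.25e-07 to 0.119). Without dim probe sets 7 list calls ended, without cross-hybridising ones 11, with only arrays A and B 5, with only arrays C and D 3, and with cyclic loess 2, namely junction genes and oxidative phosphorylation genes (0.0682, over 19 alternatives 7.45e-09 to 0.0682) in siTAZ cells. Where a list call ended, the cause was not tested.

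Direction was compared only for named genes that passed in the reported fit or under the other setting. Of all named gene results, 4488 kept their call, 10 no longer passed, 11 newly passed and 1 that had passed changed sign. That was TMT1A in sibcat cells, at -0.025 without cross-hybridising probe sets (adjusted p = 0.903), which is no longer a change past the threshold; the cause was not tested. The APC gene in APC cells passed with the mean of its probe sets (0.347), since probe sets that rose enter that mean. CTNNB1 in siTAZ cells passed with the replicate block (0.20), with the block of A and B against C and D (0.20) and with the ACTB covariate (0.40), and the APC gene differed between siTAZ and sibcat cells with these settings too (0.27, 0.27 and 0.38). On arrays a level near background limits what can be seen: 12559 of 19775 genes were at or above the median level.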

Other observations

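The lists and genes here were chosen after their values had been seen. The MHC class II and histone lists were written because several of their members stood among the most changed genes. The MHC class I list was written in the same round. Counts are therefore given without a list test. Of 12 MHC class II genes 10 rose and 0 fell in APC cells (median 3.15), 8 rose in sibcat cells (median 0.44) and 5 in siTAZ cells (median 0.24). In APC cells the class II regulator gene CIITA, with a control mean below 5.10, rose by 2.37 and CD74 by 3.16. Of 14 MHC class I and antigen processing genes 14 rose in APC cells (median 0.89) and 14 in sibcat cells (median 0.71). In siTAZ cells 10 of them rose and 1 fell (median 0.31). PSMB9 rose by 1.64 in APC, 1.15 in sibcat and 0.33 in siTAZ cells.

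Of 43 replication-dependent histone genes 17 fell and 0 rose in siTAZ cells (median -0.23), 20 fell and 0 rose in APC cells (median -0.23), and in sibcat cells 8 rose and 2 fell. H2AC6 changed by -1.11 in siTAZ, 0.64 in sibcat and -2.01 in APC cells.

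Among single genes, ID1 rose by 2.62 and ID2 fell by 4.01 in APC cells. DICER1 rose by 1.02 in siTAZ and 1.21 in sibcat cells, which received siRNAs against other genes, and differed by 0.22 in APC cells, which received the control siRNA. LAPTM5 changed by 0.40, 2.75 and -0.32, and CD14 by 0.59, 1.63 and 0.48 in siTAZ, sibcat and APC cells; PTPRC differed by -0.02 in sibcat cells.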
